A study of Homo sapiens with 6 samples.

How the data were processed

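RNA was sequenced from 6 samples of CAOV2 human ovarian cancer cells, which the labels call both a cell line and primary cancer cells. Per the labels' protocols, 100000 cells were seeded in a well, transfected for 2 days with 100 pmol of siRNA and 6 µL of a lipid reagent, and collected on day 3. The siRNA targeted TAZ in 3 samples (siTAZ) and was a non-targeting control in 3 samples (siNT). Total RNA was purified on columns, and libraries were made from 1 µg of it with a stranded poly(A) kit, per the labels' protocols. The samples were placed in their groups by their titles, which call them biological replicates. The replicate numbers used here are those of the titles. The sample descriptions carry other numbers, with a gap, which do not tell whether other samples were made. Nothing in the labels says whether they came from separate thaws or days, so the p-values measure the spread between these samples, which may be partly technical.

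Per the submitters' processing notes, FastQC, HISAT2, HTSeq and DESeq2 were used and the genome build was hg19. Their versions, the gene annotation, the strand setting of the counting and the filter on genes are not given in the sources used here. The deposited table holds 1 value per gene and sample for 17211 genes with Ensembl identifiers. The deposited values are a signal in units of reads divided by 1 size factor per library, and not raw counts. This was found from the values: within each library, 100% of them were whole multiples, within 0.001 of a read, of what 1 read is worth. Dividing by that step recovered the whole read counts behind the deposited values. The recovered totals were 28928432, 28544414 and 25478595 reads in siNT replicates 1, 2 and 3, and 28458503, 31903484 and 34488196 reads in siTAZ replicates 1, 2 and 3. The size factors ran from 0.828 to 1.17. No gene was at 0 in all 6 libraries, so genes without reads had been left out before deposit. The lowest mean value of a listed gene was 0.173. Of the 17211 genes, 7 had a mean under 1, 390 under 5 and 1751 under 10. So few low genes argue that most low genes were also left out, by a rule that is not given. A gene absent from the deposited table may therefore have had reads.

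Gene names came from a table of Ensembl identifiers, which named 15593 of the 17211 genes. Another 1150 were named from GENCODE release 29, 468 stayed unnamed, and 16 identifiers share a symbol with another. The GENCODE annotation is of GRCh38 and the authors used hg19, so it served only for names, gene types, transcript length and GC content, and no coordinates are given. A list member whose identifier in the deposited table was unnamed counts as not measured.

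The design fixed before the data were examined named edgeR's quasi-likelihood test for counts, with limma for a table of normalized values. Because the deposited values are normalized, limma 3.58.1 in R 4.3.3 was the main test. It was fitted with an intensity trend in the prior variance to log2(deposited value + 1) of the 17204 genes with a mean of at least 1, with the group as the only term and all 6 libraries. P-values were adjusted by the Benjamini-Hochberg method and the threshold was an adjusted p of 0.05. Fold changes in log2 are siTAZ over siNT on the log2(deposited value + 1) scale, which understates the change of low genes. Means, SDs and folds of means are of the deposited values. The count tests edgeR 4.0.16, DESeq2 1.42.0 and limma voom were run on the recovered reads as alternatives. Data were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

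The 26 pathway lists and 6 cell type marker lists were written before the data were examined. Each pathway list was tested with limma's camera, with a preset correlation between genes of 0.01, on the log2 values in place of the voom values the design named, and adjusted over the 26 lists. Camera with the correlation estimated from the data and fry were the alternatives. Members were called by limma over all genes and again adjusted over the list alone. Another 3 lists, used only in the closing section, were chosen after the data were seen.

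Genes to name were also fixed in advance. They are 15 genes set by name, of which NOX4 was not listed in the deposited table, and the 12 largest falls and 12 largest rises by log2 fold change. The falls and rises were taken among genes past the threshold with a mean of at least 10 and no overlap between the groups' libraries. Genes named only as LOC, LINC, MIR, SNOR, clone, antisense or accession identifiers were skipped. Up to 4 called members per list with the smallest adjusted p follow, or up to 2 uncalled members with the highest mean where none was called. Other list members are named only as examples of a count, or in the closing section, where they were chosen after their values were seen. Some genes that the rule takes are not reported here.

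Limma, edgeR, DESeq2, voom and camera with the preset correlation were tested on simulated data made from the real genes' means and library sizes. In these, 200 genes with a mean of at least 10 were changed by known folds, as many up as down. Far more genes changed in the real data, so the rates below do not cover lower genes or errors of scaling. Fry, camera with an estimated correlation and the tests against a fold of 1.2 were not tested in this way. For siTAZ against siNT, limma on 17201 genes recovered 84% of the 100 genes changed 2-fold and 73% of the 100 genes changed 1.41-fold, and 4.85% of its calls were false. On 15499 genes edgeR recovered 84% and 75% with 5.36% of its calls false, and voom 82% and 72% with 6.10% false. DESeq2 on 17211 genes recovered 79% and 71% with 4.46% false. In the same simulation camera called the 1 planted list, whose genes were all raised 2-fold, and 0 of 20 random lists. Genes were drawn independently of each other there. The result therefore does not measure how often camera calls lists whose members move together. The alternatives covered the test, the scaling, the pseudocount, the filter on low values, the 20 most abundant genes, the replicate number as a block, each library left out in turn, and a test against a fold of 1.2. A group with all libraries at 0 reads was set to a floor of 3 counts per library, and intervals at 95% and floors cover counting error only, since reads without molecular identifiers are not independent molecules.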

Results

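The transcriptome of CAOV2 ovarian cancer cells was measured after silencing of TAZ. TAZ, encoded by WWTR1, is a transcriptional coactivator of the Hippo pathway that binds TEAD factors, as does its relative YAP, encoded by YAP1. There were 3 libraries of cells transfected with siRNA against TAZ (siTAZ) and 3 of cells given non-targeting siRNA (siNT). The libraries held 25478595 to 28928432 reads in genes in siNT and 28458503 to 34488196 in siTAZ. Levels are deposited values, that is reads divided by the library's size factor, given as mean ± SD with n = 3 per group. Transcripts of the mitochondrial genome took 2.85% to 3.91% of the reads over the 6 libraries, and the 20 most abundant genes took 6.65% to 7.51%. Pearson's r of log2 values, across genes that are not independent replicates, was 0.992 to 0.995 within groups and 0.972 to 0.975 between them. No replicate was a copy of another: the chi-square per degree of freedom of their reads was 2.64 to 8.10 within groups. Of the variance between libraries, 70.3% lay on the first principal component, which parted siNT from siTAZ.

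The comparison asks which transcripts change when TAZ is silenced. WWTR1 (ENSG00000018408) fell 16.1-fold. Its values were 4359, 4217 and 4258 in the 3 siNT libraries and 242, 277 and 280 in the 3 siTAZ libraries, with a log2 fold change of -4.0 (SE 0.06, limma adjusted p = 8.0e-17). YAP1 fell far less, from 5992 ± 213 to 4875 ± 185 (log2 fold change -0.30, limma adjusted p = 4.7e-05). TAFAZZIN, a mitochondrial cardiolipin enzyme gene that once carried the symbol TAZ, fell from 800 ± 30.1 to 585 ± 25.9 (log2 fold change -0.45, limma adjusted p = 1.6e-05). Among the other YAP and TAZ readouts, ANKRD1 fell 4.75-fold, from 4428 ± 258 to 933 ± 47.4, and CCN1 (CYR61), a matricellular protein gene, fell 2.17-fold, from 5897 ± 328 to 2722 ± 157. CCN2 (CTGF), another widely used readout, did not pass the test, at 5690 ± 53.9 in siNT and 5974 ± 125 in siTAZ (log2 fold change 0.07, SE 0.04, limma adjusted p = 0.18). It passed, as higher, only under total count scaling (limma adjusted p = 0.021, range over 21 alternatives 0.021 to 0.39).

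Of 17204 genes tested, 9604 changed at an adjusted p under 0.05 in limma, 4874 of them higher and 4730 lower in siTAZ. Changes of at least 2-fold were fewer, with 1152 genes higher and 673 lower. Most of the changed genes therefore moved by less than 2-fold. Against a fold of 1.2, limma's treat test called 4417 genes and edgeR's glmTreat 5131. With genes held to at least 1 CPM in 3 libraries, 697 were at least 2-fold higher and 399 lower, and with a pseudocount of 10 they were 681 and 358. The count test on the recovered reads, edgeR's quasi-likelihood test, called 9383 genes.

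**Figure D1:**
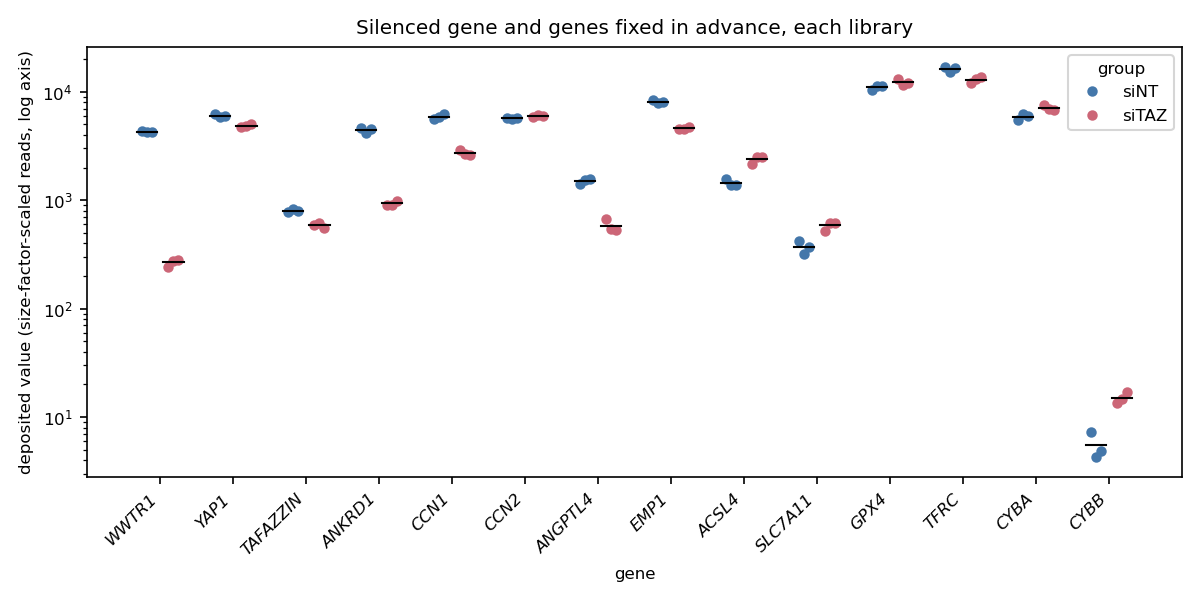
Deposited values (reads divided by the library's size factor, log axis) of the silenced gene and 13 other genes set in advance, with 1 point per library, 3 libraries per group, and a black bar at each group mean. WWTR1 lies between 242 and 280 in the siTAZ libraries and between 4217 and 4359 in the siNT libraries, while the groups of CCN2 lie near each other.

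Genes tied to ferroptosis, an iron-dependent form of cell death driven by lipid peroxidation, moved in both directions. ANGPTL4, a secreted inhibitor of lipoprotein lipase, fell 2.61-fold, from 1516 ± 82.9 to 580 ± 73.7 (limma adjusted p = 2.3e-10), and EMP1, an epithelial membrane protein gene, fell 1.74-fold, from 8033 ± 247 to 4628 ± 90.6. TFRC, the transferrin receptor for iron uptake, fell from 16296 ± 965 to 12923 ± 820. ACSL4, which loads polyunsaturated fatty acids into lipids that can be peroxidised, rose 1.65-fold, from 1449 ± 112 to 2389 ± 208. SLC7A11, the cystine importer that feeds glutathione synthesis, rose 1.58-fold, from 370 ± 53.3 to 584 ± 60.6. GPX4, the peroxidase that removes lipid peroxides, rose 1.11-fold, from 10989 ± 532 to 12185 ± 783 (limma adjusted p = 0.024). That call was lost with the replicate block (0.080), without siNT replicate 1 (0.098) and without siTAZ replicate 1 (0.091), with a range of 0.0027 to 0.098 over 21 alternatives. CYBB, the catalytic subunit of NADPH oxidase 2, was scarce and rose from 5.48 ± 1.63 to 15.1 ± 1.81 (log2 fold change 1.33, or 0.70 with a pseudocount of 10, SE 0.35, limma adjusted p = 0.0039). Its partner CYBA rose 1.21-fold, from 5878 ± 385 to 7106 ± 453.

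With the pseudocount of 1, the largest falls after WWTR1 were in UCA1, a long noncoding RNA first described in urothelial cancer, from 542 ± 7.92 to 41.7 ± 16.4, and LRRC15, a leucine-rich repeat membrane protein gene, from 34.7 ± 3.33 to 2.44 ± 1.89. VGF, a secreted neuropeptide precursor, was the most abundant of them and fell 8.56-fold, from 9188 ± 868 to 1073 ± 92.3 (log2 fold change -3.10, SE 0.07, limma adjusted p = 5.6e-15). TMEM158, a membrane protein gene induced by RAS, fell 6.78-fold to 95.4 ± 8.02, and WNT9A, a WNT ligand, fell 6.11-fold to 73.9 ± 11.5. LCK, a SRC family kinase best known from T cells, fell 7.20-fold, from 131 ± 6.44 to 18.1 ± 3.57. GLDC, the glycine decarboxylase, RYR3, a ryanodine receptor, and COL4A1, a basement membrane collagen, had log2 fold changes of -2.96, -2.71 and -2.58, from means of 18.2, 20.3 and 42.1 in siNT, and all passed the test. ALPP and C10orf55 also fell, from 22.9 ± 2.25 to 2.81 ± 2.43 and from 17.9 ± 4.89 to 2.14 ± 1.37. Both are uncertain, since ALPP has near-identical paralogs and C10orf55 overlaps PLAU on the opposite strand, while the strand setting of the counting is not given in the sources used here. The falls of these low genes stayed past the threshold, but their size and order rest mainly on the pseudocount. Over the alternatives the log2 fold change ran from -1.85 to -4.03 for LRRC15, -1.38 to -4.22 for ALPP, -1.24 to -4.27 for GLDC, -1.29 to -3.17 for RYR3, -1.19 to -3.15 for C10orf55 and -1.60 to -3.06 for COL4A1, each smallest with a pseudocount of 10, against -3.03 to -3.17 for VGF.

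The largest rises were mostly in genes near the floor in siNT. SLC6A19, a neutral amino acid transporter of gut and kidney epithelium, had 0 reads in the siNT libraries and 426 in the siTAZ libraries (133 ± 12.7), which is at least 40.0-fold higher against a floor of 3 counts per library. DEGS2, a sphingolipid desaturase gene, had 1 read in siNT and 119 in siTAZ, a ratio of 100.3 with an exact 95% interval of 17.7 to 3995. SLC13A2, a dicarboxylate transporter, rose 26.8-fold, from 10.4 ± 2.66 to 279 ± 61.6, and ANXA13, an annexin of gut epithelium, rose 32.7-fold to 96.9 ± 3.36. PLSCR4, a scramblase family member, rose 14.7-fold, from 48.7 ± 5.9 to 714 ± 20.8 (log2 fold change 3.85, SE 0.11, limma adjusted p = 6.0e-14). TM4SF20, SMIM24, HPN, a membrane serine protease, SLC23A1, an ascorbate transporter, SLC5A9, a sugar transporter, and AGT, angiotensinogen, rose by log2 fold changes of 4.33, 4.18, 3.96, 3.87, 3.85 and 3.77, each from a mean of 10.6 or less in siNT. CES5AP1 rose by 4.25 on the same scale, but it is a pseudogene and part of its reads could belong to a related carboxylesterase gene. With a pseudocount of 10, TM4SF20, SMIM24, HPN, SLC23A1, SLC5A9, AGT and CES5AP1 rose by 2.68, 3.02, 2.22, 2.40, 2.02, 2.93 and 2.88, and PLSCR4 by 3.63.

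**Figure D2:**
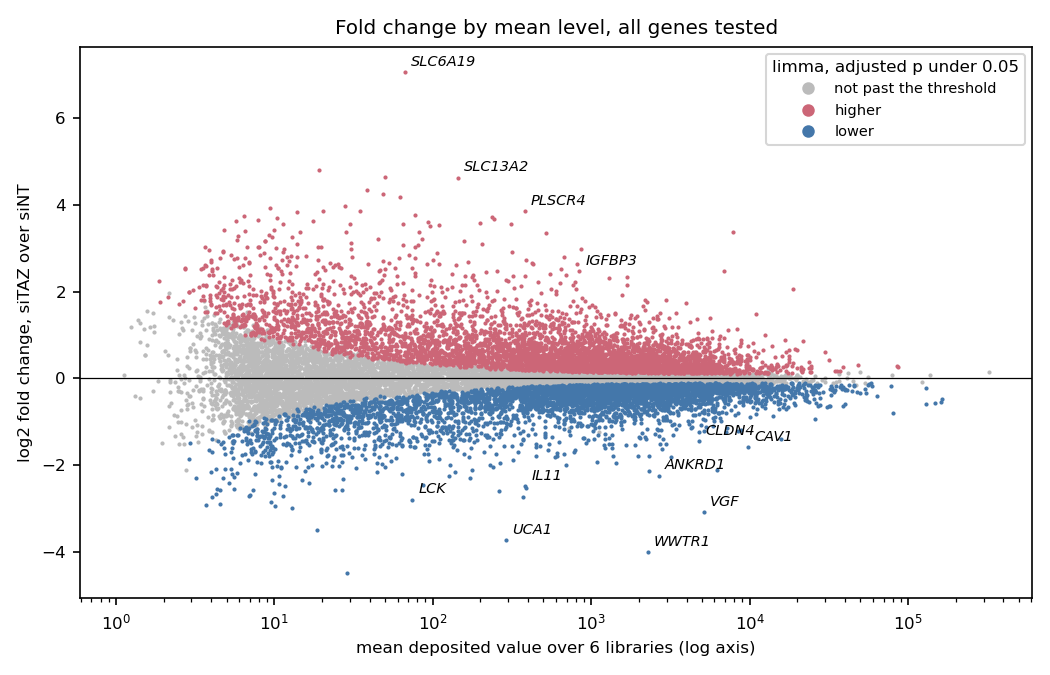
Log2 fold change of siTAZ over siNT against the mean deposited value over the 6 libraries (log axis), with 1 point for each of the 17204 genes tested and colour showing limma's call. VGF lies at -3.10 among abundant genes and WWTR1 at -4.0.

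Of the 26 pathway lists, 10 passed limma's camera with the preset correlation of 0.01, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.40 and 2 lists had an unadjusted p under 0.05. Fry, which does not compare a list with other genes, called 20. Other groupings of the 6 libraries, each mixing siNT with siTAZ, gave 3 to 8 lists by camera with the preset correlation. The member counts below are limma's calls over all genes, and counts adjusted over the list alone are given where they differ. For scale, 4874 of all 17204 genes tested were called higher and 4730 lower. Among genes with a mean of 1000 or more, 4335 of 6343 were called. Member counts near these shares do not set a list apart from other genes.

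Most listed genes of cell division fell by small amounts. Of 37 mitosis genes, 28 fell, 0 rose and 9 did not pass, with a median log2 fold change of -0.27 (limma camera adjusted p = 1.4e-07; adjusted p = 0.40 with an estimated correlation). ANLN, the anillin of the cleavage furrow, fell 2.33-fold, from 11824 ± 608 to 5070 ± 168, and the kinesin KIF23 and the kinase AURKA fell 1.65-fold and 1.49-fold. Of 37 genes of DNA replication and E2F targets, 29 fell, 1 rose and 7 did not pass, with a median of -0.30 (limma camera adjusted p = 3.2e-07; adjusted p = 0.40 with an estimated correlation). Adjusted over the list alone, 2 rose and 29 fell. RRM2, a subunit of ribonucleotide reductase, fell 1.85-fold, from 13048 ± 542 to 7063 ± 171, and cyclin E1 (CCNE1) fell 1.54-fold. Of 50 cytosolic ribosomal protein genes, 41 fell, 1 rose and 8 did not pass, with a median of -0.19 (limma camera adjusted p = 3.2e-07; adjusted p = 0.40 with an estimated correlation). With p-values adjusted over the list alone, 42 fell. RPS20 fell 1.40-fold and RPL15 1.34-fold, and the many processed copies of these genes make single members uncertain. Ribosomal protein transcripts took 4.31% to 4.51% of reads in siNT and 3.79% to 4.05% in siTAZ.

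Actin and SRF target genes fell in 18 of 24 cases, rose in 2 and did not pass in 4, with a median of -0.44 (limma camera adjusted p = 1.6e-05; adjusted p = 0.40 with an estimated correlation). TAGLN, transgelin, fell 3.55-fold, from 264 ± 14 to 74.2 ± 11.4, and cytoplasmic gamma actin (ACTG1) fell 1.73-fold, from 101272 ± 4203 to 58456 ± 3978. VIL1, villin of the epithelial brush border, rose 2.62-fold, from 3120 ± 300 to 8178 ± 280. Of 24 immediate early genes, 15 fell, 5 rose and 4 did not pass, with a median of -0.41 (limma camera adjusted p = 0.018; adjusted p = 0.60 with an estimated correlation). Adjusted over the list alone, 6 rose and 15 fell. The AP-1 subunits FOSL1, FOSL2 and JUNB fell 2.07-fold, 1.90-fold and 1.83-fold. Of 19 inflammatory cytokine and NF-kB target genes, 11 fell, 2 rose and 6 did not pass, with a median of -0.36 (limma camera adjusted p = 0.016; adjusted p = 0.40 with an estimated correlation). The cytokine IL11 fell 5.64-fold, from 652 ± 43.9 to 116 ± 18.9, CSF2 (GM-CSF) fell 3.75-fold and BIRC3, an inhibitor of apoptosis, fell 3.89-fold, while TNFAIP2 rose 1.47-fold.

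Metabolic lists moved in different directions. Of 25 genes of hypoxia and glycolysis, 15 fell, 3 rose and 7 did not pass, with a median of -0.27 (limma camera adjusted p = 0.0010; adjusted p = 0.40 with an estimated correlation). Lactate dehydrogenase A (LDHA) fell 1.92-fold, from 33847 ± 1086 to 17596 ± 547, PGAM1 fell 1.94-fold and HK2 1.51-fold, whereas carbonic anhydrase IX (CA9), a hypoxia marker, rose 5.03-fold, from 53.2 ± 15.4 to 267 ± 15.3. Of 24 cholesterol biosynthesis genes, 15 rose, 3 fell and 6 did not pass, with a median of 0.27 (limma camera adjusted p = 0.0017; adjusted p = 0.40 with an estimated correlation). The sterol enzyme genes SC5D and SQLE rose 1.78-fold, from 1834 ± 179 to 3258 ± 342, and 1.56-fold, from 2072 ± 32.1 to 3233 ± 69.5. Of 25 PPAR target and fatty acid oxidation genes, 12 rose, 4 fell and 9 did not pass, with a median of 0.17 (limma camera adjusted p = 0.044; adjusted p = 0.40 with an estimated correlation). There were 13 rises adjusted over the list alone. PDK4, a kinase that restrains pyruvate dehydrogenase, rose 2.36-fold, from 289 ± 36.2 to 683 ± 45.9, while the lipid droplet protein PLIN2 fell 1.43-fold. This list's camera call was also lost with the 1 CPM filter (0.074), the replicate block (0.054), and without siNT replicate 1 (0.053), siNT replicate 3 (0.053), siTAZ replicate 1 (0.055) or siTAZ replicate 3 (0.055), with a range of 0.00029 to 0.40 over 19 alternatives.

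Epithelial genes rose in 13 of 20 cases, fell in 4 and did not pass in 3, with a median of 0.45 (limma camera adjusted p = 0.018; adjusted p = 0.40 with an estimated correlation). There were 14 rises adjusted over the list alone. The adhesion molecule EPCAM rose 2.72-fold, from 501 ± 10.3 to 1361 ± 42, and the transcription factor ELF3 rose 2.31-fold, from 1746 ± 161 to 4025 ± 185. Against that direction, keratin 7 (KRT7) fell 2.66-fold, from 22847 ± 1266 to 8604 ± 879, and the tight junction gene CLDN4 fell 2.73-fold. The 16 mesenchymal genes did not pass (3 rose, 7 fell and 6 did not pass, median -0.28, limma camera adjusted p = 0.27). Vimentin (VIM) fell 1.48-fold and S100A4 fell 2.13-fold, while TCF4 rose 3.13-fold and SPARC 1.97-fold.

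The list of YAP and TAZ core targets did not pass camera, with 10 of 21 members lower, 6 higher and 5 not passing, and a median of -0.17 (limma camera adjusted p = 0.11). Adjusted over the list alone, 11 fell and 6 rose. Beside the falls of ANKRD1 and CCN1, IGFBP3, a binding protein of insulin-like growth factors, rose 5.48-fold, from 260 ± 56.3 to 1425 ± 113, and NT5E (CD73) rose 1.92-fold, from 4740 ± 141 to 9081 ± 408. Of 26 Hippo pathway components, 6 rose and 11 fell (median -0.09, limma camera adjusted p = 0.36), among them AMOTL2, which fell 1.73-fold, and VGLL4, which rose 1.39-fold.

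The ferroptosis lists did not pass camera either. Of 18 drivers, 9 fell, 3 rose and 6 did not pass (median -0.12, limma camera adjusted p = 0.11), and the elongase ELOVL5 fell 2.21-fold. Of 25 suppressors, 10 rose, 4 fell and 11 did not pass (median 0.08, limma camera adjusted p = 0.27). CBS, a transsulfuration enzyme, rose 2.91-fold, the lipid acyltransferase MBOAT1 rose 2.18-fold, and TXNRD1, thioredoxin reductase, fell 1.53-fold. Of 24 NRF2 targets, 11 rose, 4 fell and 9 did not pass (median 0.13, limma camera adjusted p = 0.19). ABCC3, an efflux transporter, rose 3.41-fold and NQO1 rose 1.76-fold. AKR1C3 rose 2.58-fold, and its reads can be shared with close paralogs. Of 20 iron handling genes, 7 rose and 7 fell (median 0.01, limma camera adjusted p = 0.90). The iron exporter SLC40A1 rose 2.95-fold and ferritin heavy chain (FTH1) fell 1.53-fold, from 33604 ± 2351 to 21934 ± 2928. Of 10 NADPH oxidase genes, 5 rose and 3 fell. DUOX2 rose from 3.60 ± 4.29 to 24.1 ± 8.29 and RAC1 fell 1.44-fold. This list's median was -0.06 and its mean 0.45, and camera's direction was down (limma camera adjusted p = 0.94).

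**Figure D3:**
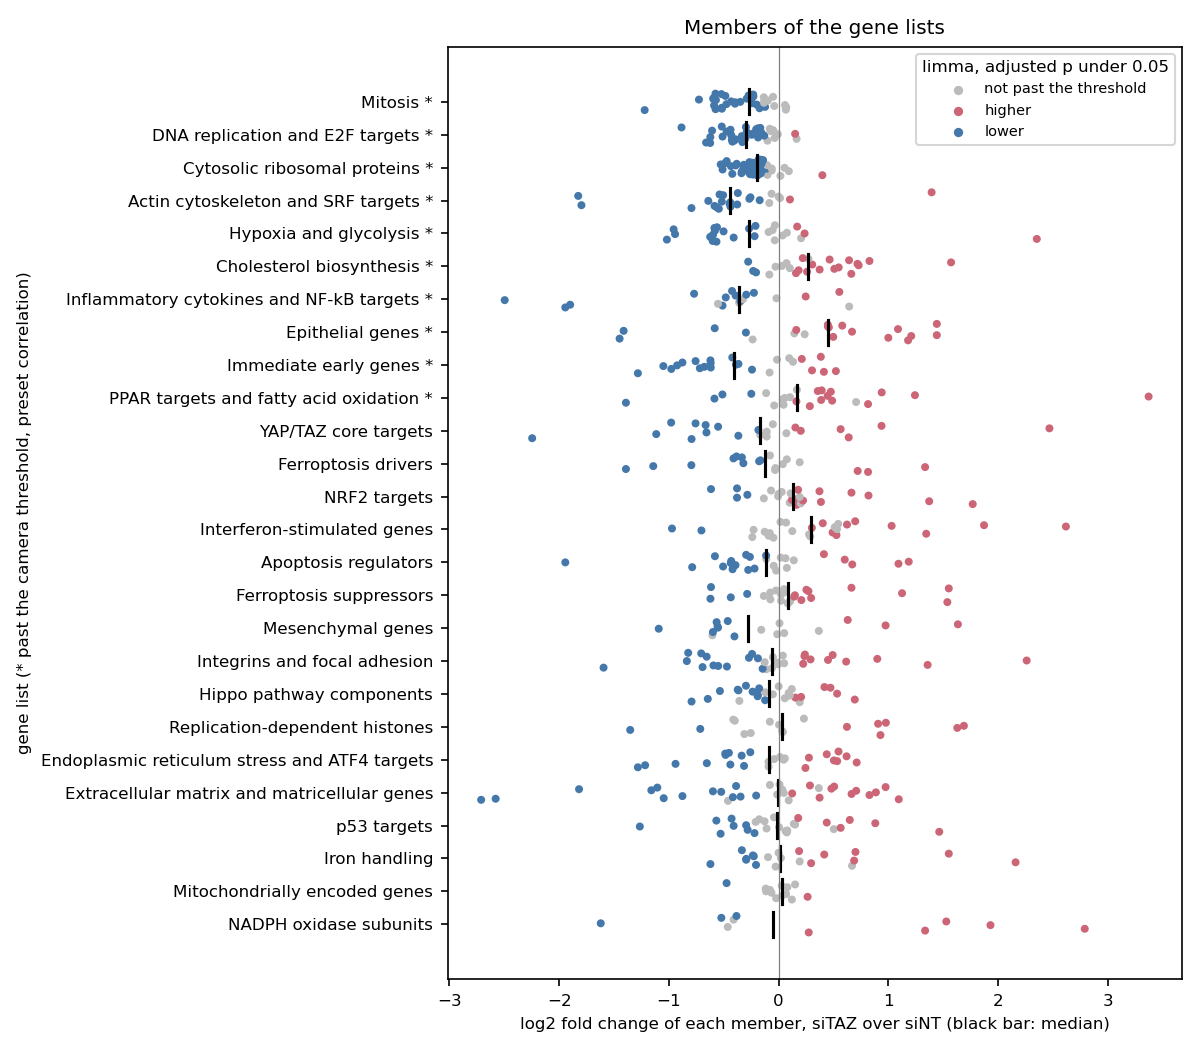
Log2 fold change of siTAZ over siNT for each tested member of the 26 pathway lists, with 1 point per gene coloured by limma's call, a black bar at each list's median, and a star after lists past camera's threshold with the preset correlation. Most members of the mitosis, replication and ribosomal lists lie below 0, with ANLN at -1.22, while the YAP and TAZ target list spreads from -2.25 to 2.47.

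Of the other lists, none passed camera with the preset correlation. Of 26 interferon-stimulated genes, which also respond to transfected RNA, 10 rose and 2 fell (median 0.30, or 0.28 with 2 members of 3 reads or fewer in a group at their bound, limma camera adjusted p = 0.19). There were 9 rises adjusted over the list alone. OAS1 rose 2.04-fold and ISG15 fell 1.96-fold. Of 25 apoptosis regulators, 5 rose and 13 fell (median -0.11, limma camera adjusted p = 0.27), or 6 and 13 adjusted over the list alone. BMF, which promotes apoptosis, rose 2.27-fold and BCL2L1, which restrains it, fell 1.42-fold. Of 31 integrin and focal adhesion genes, 10 rose and 13 fell (median -0.06, limma camera adjusted p = 0.32), or 10 and 15 adjusted over the list alone. ITGB4 rose 4.70-fold and caveolin 1 (CAV1) fell 3.02-fold, from 14689 ± 356 to 4867 ± 286. Of 32 extracellular matrix genes, 11 rose and 13 fell (limma camera adjusted p = 0.86). LAMC1 rose 1.85-fold and the collagenase MMP1 fell 3.50-fold. Of 25 genes of endoplasmic reticulum stress and ATF4, 8 rose and 11 fell (median -0.09, limma camera adjusted p = 0.40). XBP1 rose 1.46-fold and CHAC1 fell 2.34-fold.

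Of 26 p53 targets, 6 rose and 8 fell, with a median of -0.02 and a mean of 0.02, where camera's direction was down (limma camera adjusted p = 0.90). BTG2, which restrains growth, rose 2.77-fold and the death receptor TNFRSF10B fell 1.48-fold. Of 17 replication-dependent histone genes, 6 rose and 2 fell (median 0.03, limma camera adjusted p = 0.36). Most of these transcripts lack poly(A) tails and the libraries were made with a poly(A) kit. The values therefore do not measure their total level. H2BC12 rose 3.22-fold and H2AC20 fell 2.63-fold, and near-identical histone copies make both uncertain. Of 13 mitochondrially encoded genes, 1 rose and 1 fell, with a median of 0.03 and a mean of -0.01, where camera's direction was down and turned up under total count scaling (limma camera adjusted p = 0.90, or 0.91 under that scaling, range over 19 alternatives 0.31 to 0.96). MT-CO1 rose from 78858 ± 7573 to 94801 ± 10868 (limma adjusted p = 0.0066), a call lost without siNT replicate 2 (0.054) and in DESeq2 (0.063), with a range of 0.00039 to 0.063 over 20 alternatives. MT-ND6 fell 1.38-fold and lies antisense to other mitochondrial transcripts, so its value rests on the strand setting.

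Markers of other cell types were mostly absent from the deposited table or low, except in the fibroblast list. Its 6 tested members had a median mean of 737, against 476 over all listed genes. Of 8 erythroid markers 0 were tested, and of 10 endothelial markers only ESAM was, which fell from 1774 ± 99.9 to 1165 ± 109. Of 12 leukocyte markers, 4 were tested and 2 rose, LYZ from 20.9 ± 1.92 to 127 ± 18.8 and CD14 from 61.9 ± 8.08 to 115 ± 1.36. Of 11 fibroblast markers, 6 were tested, and COL3A1, PDGFRA and PDGFRB rose while COL1A2 fell, from 12.6 ± 2.69 to 1.30 ± 1.14. LUM was the most abundant, at 3797 ± 362 in siNT and 3885 ± 358 in siTAZ, and did not pass the test. Of 9 mesothelial markers, 4 were tested. CALB2 fell from 62.6 ± 10.3 to 22.2 ± 3.81, and MSLN, which is also an ovarian carcinoma marker, rose from 2.63 ± 1.38 to 7.64 ± 3.29 (limma adjusted p = 0.043). The labelled tumour type has markers of its own. Of 11 Müllerian and ovarian carcinoma markers, 5 were tested. MECOM rose from 892 ± 26.5 to 1253 ± 93, and FOLR1, from 5.90 ± 0.60 to 16.2 ± 1.27, and MSLN also rose. PAX8 was at 28.8 ± 13.9 and 18.2 ± 3.28 and MUC16 at 11.9 ± 3.67 and 7.98 ± 1.55, neither passing the test.

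All of these values come from 1 siRNA reagent against TAZ and 1 control reagent in CAOV2 cells.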

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

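After seeing the data, 3 alternatives were added: edgeR's test on the recovered reads, which the design had named for raw counts, TMM scaling in limma, and limma's treat. The numbers of changed genes moved by over 1.5 times only when a fold of 1.2 was built into the test. Then edgeR's glmTreat gave 5131 genes (2876 higher, 2255 lower) and limma's treat 4417 (2497 higher, 1920 lower), as a stricter null hypothesis must. With genes held to 1 CPM in 3 libraries, which tests 13461 genes, 697 were at least 2-fold higher and 399 lower. With a pseudocount of 10, which shrinks the folds of low genes, they were 681 and 358. The other settings gave 8538 to 9674 changed genes, DESeq2 giving 8752 and voom 9391, and leaving out 1 library gave 8538 to 9674. Total count scaling moved the balance of calls most, to 5561 higher and 4046 lower from 4874 and 4730. No gene called by both the main test and an alternative changed direction. WWTR1 stayed lower and past the threshold in its 21 alternatives, by -3.94 to -4.04. The replicate numbers do not pair the samples: the deviations of same-numbered samples correlated at -0.53, -0.30 and -0.087 over 11466 genes, and no sample correlated best with its own number. With the replicate block, 8701 genes and 9 lists passed. Of the 10 lists past camera, 0 remained with an estimated correlation, and fry gave 20; the cause was not tested. Among named genes, 2670 results kept their side of the threshold, 1 gained it (CCN2) and 5 lost it (GPX4 and MT-CO1); among lists, 457 kept it, 10 gained it under fry and 16 lost it. A direction turned only in 10 tests of lists that passed in neither setting, and the cause was not tested. With 1 CPM in 3 libraries these were the matrix and iron lists (both adjusted p = 0.95), with fry the matrix (0.83) and p53 (0.34) lists, and with total count scaling the mitochondrial list (0.91). Leaving out 1 library turned the mitochondrial list (adjusted p = 0.59 without siNT replicate 1, 0.78 without siTAZ replicate 1, 0.85 without siTAZ replicate 3, range over the 6 libraries 0.31 to 0.85) and the NADPH oxidase list (0.88 without siNT replicate 2, 0.98 without siTAZ replicate 3, range 0.78 to 0.99). Of genes with a mean under 10, 390 of 1744 tested passed, against 4335 of 6343 at a mean of 1000 or more; how much of that gap depth sets was not tested.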

Other observations

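Many genes known from gut epithelium and liver were higher in siTAZ. The 3 lists below, and the test of intestinal cells, were chosen after the data were seen, and the first list was drawn up with the largest rises in view. The counts describe the lists, and no set test of them is given, since the lists were not chosen independently of the result. Of 53 gut epithelial genes, 40 were tested. Of these, 37 rose and 1 (EZR) fell, with a median log2 fold change of 1.67, or 1.58 with the 5 members of 3 reads or fewer in a group at their bound. Genes without reads in siNT, such as SLC6A19 and APOB, could be tested only through their reads in siTAZ. That tilts the counts of these lists toward rises. Without the members among the 12 largest rises, 32 of 35 rose and 1 fell, with a median of 1.49. The rises included abundant transcripts: CDH17, liver-intestine cadherin, rose from 5754 ± 264 to 16127 ± 118 (SD, n = 3), VIL1 from 3120 ± 300 to 8178 ± 280, and the brush border scaffold USH1C from 224 ± 1.68 to 1405 ± 75.7. The trefoil factors TFF1, TFF2 and TFF3 rose from 582 to 1548, from 146 to 404 and from 363 to 1024. CDH17 and VIL1 were thus already abundant in siNT, as was HNF4A at 3621, while of the 5 tested Müllerian and ovarian carcinoma markers MECOM was at 892 there and PAX8, MUC16, FOLR1 and MSLN were at 28.8 or less. The identity of the cells was not tested here.

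Of 25 transcription factors of gut and liver, 19 were tested. Of these, 16 were higher at an adjusted p under 0.05 in limma and 1 (KLF4) was lower, with a median of 0.49. CDX2, a regulator of intestinal identity, rose from 290 ± 27.1 to 844 ± 34.1 and HNF4A from 3621 ± 191 to 5486 ± 295. Of 20 genes of proteins secreted by hepatocytes, 13 were tested. Of these, 12 rose and 0 fell at an adjusted p under 0.05 in limma, and RBP4 did not pass. Their median was 2.04, or 1.78 with 1 member of 3 reads or fewer at its bound. Without AGT, which is among the 12 largest rises, 11 of 12 rose and 0 fell, with a median of 1.91. SERPINA1, alpha-1 antitrypsin, rose from 29.9 ± 2.36 to 369 ± 62.4 and TTR, transthyretin, from 8.32 ± 3.08 to 81.9 ± 4.93, both still low, and albumin (ALB) reached 22.3.

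Mature intestinal cells in the siTAZ libraries were one candidate source of the gut epithelial genes. Such cells hold FABP1, APOA1, APOA4 and KRT20 at high levels, yet the largest gain among these was 486 ± 55.6 deposited units (SE), for FABP1, against 5058 ± 237 for VIL1. APOA1 gained 60.8, KRT20 15.2 and APOA4 3.33. Removing the trend of the fold change on GC content and gene length left the list's median at 1.67. These values argue against mature intestinal cells and against a GC or length trend as the whole cause. Cells of another gut-like line were not tested and stay open, as do effects of the siRNA on transcripts other than WWTR1, since 1 reagent was used. The silencing of TAZ, which the design names, remains an untested hypothesis for this pattern.

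Among genes past 2-fold, 63.1% were higher in siTAZ. The siTAZ libraries were on average deeper, but after thinning each library to 25478595 reads the share was 62.3% in the mean of 5 draws (62.1% to 62.5%). Under TMM, upper quartile and total count scaling the share was at least 63.2%, and it was 67.7% under total counts. Each of these moved the median log2 fold change of all genes up, from -0.0013 to at most 0.052, which favours rises. They cannot show what a shift the other way would do to the share. Among genes with a mean of 100 or more it was 63.9% (421 against 238), so low genes alone do not give the asymmetry. The exact 95% interval was 60.1% to 67.6%, with genes taken as independent, so it does not measure the spread between libraries. At a mean of 1000 or more the share was 54.3% (88 against 74, interval taken in the same way 46.3% to 62.2%). For the most abundant genes an excess of rises was thus not detectable, and what sets that limit stays open beside TAZ silencing.

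Most members of the mitosis, replication and ribosomal lists fell, by small amounts that a scaling or composition effect could give. Camera with an estimated correlation, 0.28, 0.10 and 0.45 in turn, passed none of the 3 lists (adjusted p = 0.40 each). After removing the trend on GC content and gene length, which explained 2.66% of the variance of the fold changes over 16737 genes, the medians were -0.33, -0.31 and -0.17, against -0.27, -0.30 and -0.19 before. The scaling that moved them nearest to 0, total counts, left -0.22, -0.25 and -0.14, and each 95% bootstrap interval over members, taken as independent, excluded 0. The GC and length values argue against that trend as the whole cause. The scalings themselves differed little: the median log2 fold change of all genes was -0.00016 under upper quartile and 0.052 under total count scaling. They could thus move the list medians only by small amounts, so this test cannot decide on a larger composition effect. A slower division of the silenced cells is a hypothesis these RNA levels cannot test, and TAZ silencing and effects of the reagent on other transcripts stay open.

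The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For each count, 1 of the 10 splits, the real one, gave a result as large. The real split gave 9604 changed genes (4874 higher, 4730 lower, 1152 and 673 of them past 2-fold) in limma, and the highest of the other splits gave 0 for each of these counts. The real split gave 10 lists past camera and the highest other split gave 8. Every other split mixes siNT with siTAZ, which puts the difference between the groups into the spread that limma measures.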
